A study of Mus musculus with 15 samples.

How the data were processed

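The deposited scanner files hold 1-channel Cy3 values, extracted per the file headers with Agilent Feature Extraction 10.7.3.1. Per the file headers, the intensity of a spot was background subtracted and detrended within the array, with small or negative values replaced by a surrogate, and no scaling between arrays was applied to it. The labels state that RNA was labelled through double-stranded cDNA. Whether the strand of a transcript was told apart was not examined. The deposited series matrix holds log2 values whose preparation the authors do not state in the labels used here. Its 6 PSC columns have a median of 6.95 and its 9 cancer cell columns 6.90, each cell type shares 1 set of quantiles, the floor is 5.65, and its columns correlate with log2 mean signal at r = 0.995 to 0.999. It therefore served only as an alternative within a cell type.

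From the scanner files log2 of the processed signal was taken and each array's 75th percentile subtracted. Per array this percentile was 913 to 1449 in signal units, and 54.3% to 63.8% of spots were well above background. The 300 probes spotted 10 times were averaged, giving 56605 probes from 59305 spots. RefSeq names served to update gene names only: 33903 probes by accession, 9458 by symbol and 488 by synonym, while 12756 kept the name in the file, for 36994 names. Coordinates are those in the files, build mm9. Spots marked as outliers by the scanner software were left out. The probe with the highest mean over all 15 arrays stood for its gene, and a gene was tested if that probe was well above background on all arrays of at least 1 group of the fit. Where a group had no array well above background, "at least N-fold" compares the other group with the higher of each array's floor and its reading, and is a lower bound.

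Differences were fitted with limma 3.58.1 in R 4.3.3, with 1 fit for the PSC arrays, 1 for the cancer cell arrays and 1 for the comparison of cell types, moderated variances and Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05. Lists were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, where at least 5 members were tested. The 44 lists were written from general knowledge before the data were examined, as were the comparisons, threshold, named-gene rule and most alternatives. Also used were the R package data.table (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

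Genes are named by rule: up to 10 largest rises and falls past the threshold whose groups do not overlap, filled to 5 by smallest p where fewer pass, up to 4 members per list past camera, and a few markers fixed in advance. Clone and predicted names were left out. Results of a few genes that the rule would name are not reported here.

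The procedure was tested on simulated data drawn independently for each gene with its own spread, in which about 67 genes were changed at each size. At log2 changes of 0.5, 1 and 2 it called 32.8%, 65.7% and 92.4% for the PSC genotypes, 59.7%, 82.1% and 97% for WT PSC medium and 10.4%, 55.2% and 81.8% for the cell types. Of unchanged genes it called 7 of 20627, 13 of 19413 and 2 of 21661, and none in the wrong direction. The list shifted by 0.5 was called in each of the 3 and 0 others were. Because genes were drawn independently, this does not test how often lists are called falsely when their members move together. Within a slide, a group with 1 array is assumed to vary like the others of the fit. Precision is limited by the number of arrays, 3 per group.

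Alternatives changed background correction (normexp, offset 50), scaling, the filter, the probe per gene, blocks for slide or replicate, variance model, arrays in the fit and threshold. Control spots were left out of the tests, and the series matrix was not used across cell types.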

Results

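Gene expression was measured on 1-colour Agilent mouse arrays in 15 samples that fall into 5 groups of 3. Pancreatic stellate cells (PSC) are the fibroblast-like cells of the pancreas, which store retinoids at rest and produce contractile proteins and matrix once activated. PSC came from wild-type mice (PSC WT) or heterozygous mice (PSC HT) and were cultured for 2 weeks until activated. Mouse pancreatic cancer cells made up the other 9 samples, after 24 h in control medium or in medium conditioned by WT or HT PSC (WT PSC medium and HT PSC medium). The heterozygous locus and the cancer cell line are not named in the labels used here. Between 54.3% and 63.8% of the spots of an array were well above background, no spot was saturated, and the 75th percentile of the processed signal was 913 to 1449. The labels do not say whether the replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Values are log2 signals relative to each array's 75th percentile, and differences are log2 fold changes ± SE with n = 3 arrays per group and limma's adjusted p unless stated.

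The arrays lay on 2 slides, each holding arrays of every group. In the 6 PSC arrays, the first principal component took 58.9% of the variance over 18822 genes and separated the genotypes, with scores of -29.4 to -19.0 for WT and 18.6 to 35.1 for HT. In the 9 cancer cell arrays, the first component took 35.5% over 18577 genes. The controls scored 11.2 to 32.8 on it and the 6 arrays in PSC medium -22.1 to 1.04, with WT and HT PSC medium intermixed. The second component of the cancer cells (23.2%) ranged from 3.27 to 22.1 on slide 2 and from -15.5 to 4.13 on slide 1.

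**Figure D1:**
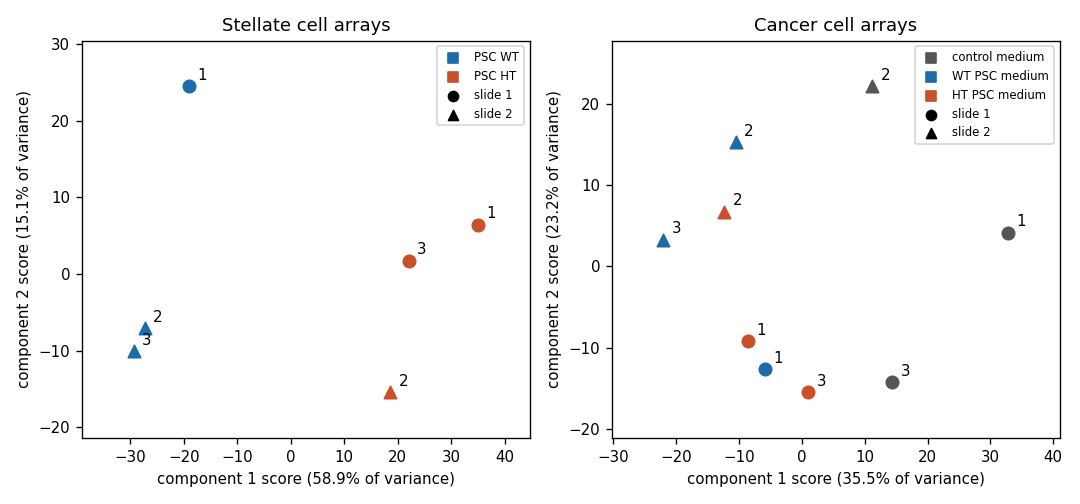
Scores of each array on the first and second principal components (no unit) of the 6 stellate cell arrays (left) and the 9 cancer cell arrays (right), coloured by group, shaped by slide and numbered by replicate. Component 1 of the stellate cells parts WT (-29.4 to -19.0) from HT (18.6 to 35.1), and component 1 of the cancer cells parts control medium (11.2 to 32.8) from the PSC media (-22.1 to 1.04).

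The first question was how activated PSC of the 2 genotypes differ. Of 26 macrophage and leukocyte markers 19 were higher in PSC HT than in PSC WT. Clec4e, a C-type lectin receptor of myeloid cells, was at least 7.24-fold higher (adjusted p = 0.00989), and Itgax, the integrin CD11c, was higher by 3.52 ± 0.53, with 2 of 3 WT arrays well above background. Of 16 mesothelial and 14 endothelial markers 9 and 8 were lower in PSC HT, among them the uroplakin Upk3b (-2.70 ± 0.19) and the endothelial sialomucin Emcn (-2.95 ± 0.15). None of these 3 lists passed with an estimated correlation (adjusted p = 0.411, 0.411 and 0.234 with an estimated correlation). That test also called 0 of 44 lists between PSC WT and cancer cells, again on 6 arrays. Not passing it therefore does not show that a list was unchanged. Acta2 (0.27 ± 0.07, adjusted p = 0.0718) and Col1a1 (0.09 ± 0.14, adjusted p = 0.794), the smooth muscle actin and type I collagen chain typical of activated stellate cells, did not pass the threshold. With slide as a block Upk3b and Emcn had -2.57 and -3.06, within slide 1 -2.46 and -3.17, and within slide 2 -2.68 and -2.94. In all, 1613 of 20851 genes passed an adjusted p of 0.05, 612 higher and 1001 lower in HT. Of these, 211 and 371 differed by at least 2-fold. The slope of the spike-in controls, given below, was lower on all WT arrays and PSC HT 2 than on PSC HT 1 and 3. Its effect on these counts was not tested.

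Of 26 macrophage and leukocyte markers tested, 19 rose in PSC HT and 0 fell (20 and 0 adjusted over the list alone). Their median was 2.42 (camera adjusted p = 1.67e-11, adjusted p = 0.411 with an estimated correlation). This was 2.15 with slide as a block, 2.07 within slide 1 and 2.15 within slide 2. The lysozymes Lyz2 (2.42 ± 0.43) and Lyz1 (2.45 ± 0.44), which digest bacterial walls, rose, and Lyz2 stood at 6.05 in HT against 3.62 in WT. Further genes with large rises that macrophages express were Fcgr2b (3.53 ± 0.76, an inhibitory Fc receptor), Alox5 (3.44 ± 0.67, 5-lipoxygenase), C5ar1 (3.40 ± 0.75, the C5a receptor), Ms4a7 (3.31 ± 0.55), Msr1 (3.18 ± 0.58, a scavenger receptor) and Ly86 (3.16 ± 0.54). Of these, Alox5 was well above background on 1 of 3 WT arrays and Fcgr2b, C5ar1 and Msr1 on 2 of 3, so their differences rest in part on readings near or below the floor. Ccl12 rose by 3.48 ± 0.74, and Nxpe5, not well above background in WT, was at least 4.16-fold higher. Ptprc, the leukocyte antigen CD45, was chosen after its values were seen because its probes disagreed: the brightest, at 1.88 in WT, 1.72 in HT and 1.71 in cancer cell controls, gave -0.16, while a dimmer probe with a transcript accession read -1.72 in HT and -4.82 in WT (3.09). Itgam, the integrin CD11b, was also chosen after its values were seen. Its brighter probe read 5.19 in WT and 5.14 in HT (-0.05), and its dimmer probe -5.61 and -5.46 (0.155). In cancer cell controls these probes read 3.13 and -5.45. The brighter probe thus also gave signal in cancer cells and the dimmer was near the floor, so they do not settle whether Itgam changed.

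Antigen presentation genes of the list for antigen-presenting fibroblasts and MHC class I were also higher in PSC HT: 7 of 13 rose and 0 fell (8 and 1 adjusted over the list alone), with a median of 0.69 (adjusted p = 8.33e-07, adjusted p = 0.343 with an estimated correlation). The median was 0.77 with slide as a block, 0.85 within slide 1 and 0.68 within slide 2. The list's median level was 2.08 to 2.21 on the WT arrays and 2.855 to 2.871 on the HT arrays. That of the macrophage markers was highest on array 1 of each genotype (-0.61 in WT, 1.67 in HT). Whether single members follow the macrophage markers between arrays was not tested. H2-Ab1, an MHC class II chain that the macrophage list also holds, rose by 1.61 ± 0.11, and the class I genes H2-D1 and H2-K1 by 0.88 ± 0.09 and 0.80 ± 0.08. Interferon response genes had a median of 0.38 (adjusted p = 1.59e-05, adjusted p = 0.601 with an estimated correlation). It was 0.46 with slide as a block, 0.52 within slide 1 and 0.34 within slide 2. Of 34, 6 rose and 0 fell (10 and 1 adjusted over the list alone), including the antiviral 2'-5' oligoadenylate synthetases Oas1a (1.25 ± 0.08) and Oas2 (1.25 ± 0.15) and the immunoproteasome subunit Psmb8 (1.00 ± 0.10). Among cytokines and chemokines 7 of 29 rose and 2 fell (10 and 3 adjusted over the list alone). That list had a median of 0.12 (adjusted p = 0.0415, adjusted p = 0.406 with an estimated correlation). This was 0.15 with slide as a block, 0.23 within slide 1 and 0.20 within slide 2. Like the macrophage markers, the cytokine list had its highest median level on array 1 of each genotype. That level was -0.717 in HT, against -1.93 and -1.63 on arrays 2 and 3, and -1.80 in WT, against -2.46 and -2.35. Ccl3 (3.02 ± 0.50) and Ccl11 (1.27 ± 0.10) rose, while Cxcl12, a chemokine of stromal cells, fell by 1.37 ± 0.07 and the alarmin Il33 fell by 1.59 ± 0.26.

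Mesothelial markers fell: 9 of 16 were lower, 0 higher (11 and 0 adjusted over the list alone), with a median of -1.30 (adjusted p = 2.33e-10, adjusted p = 0.411 with an estimated correlation). The median was -1.22 with slide as a block, -1.16 within slide 1 and -1.41 within slide 2. Besides Upk3b, the uroplakin Upk1b (-2.24 ± 0.13), the zinc finger protein Bnc1 (-2.16 ± 0.13) and the mesothelial transcription factor Wt1 (-1.16 ± 0.08) fell. Gata4, a transcription factor of the splanchnic mesoderm, fell by 2.85 ± 0.16. Of 14 endothelial markers 8 fell and 1 rose (9 and 2 adjusted over the list alone), with a median of -0.97 (adjusted p = 1.43e-06, adjusted p = 0.234 with an estimated correlation). It was -0.87 with slide as a block, -1.02 within slide 1 and -0.86 within slide 2. Cdh5, the VE-cadherin of endothelial junctions (probe at chromosome 8, 106668159 to 106668218, mm9), was at least 1.95-fold lower, and the adhesion molecule Esam fell by 2.56 ± 0.12. Flt1, a VEGF receptor, was the member that rose, by 1.53 ± 0.07. Myct1, at least 2.12-fold lower, is also expressed in endothelium. Schwann cell and nerve markers, with 3 of 8 lower and 0 higher (4 and 1 adjusted over the list alone), had a median of -0.31 (adjusted p = 0.0402, adjusted p = 0.447 with an estimated correlation). This was -0.29 with slide as a block, -0.50 within slide 1 and -0.16 within slide 2. Mbp, a myelin protein, fell by 1.59 ± 0.14 and S100b by 0.67 ± 0.10. Other genes with the largest falls were Samd12 (at least 4.39-fold), the calcium-dependent kinase Camk4 (at least 3.12-fold), Mlana (at least 2.6-fold), Zbtb8b (at least 2.47-fold) and Unc13c (-2.88 ± 0.20, well above background on 2 of 3 HT arrays).

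**Figure D2:**
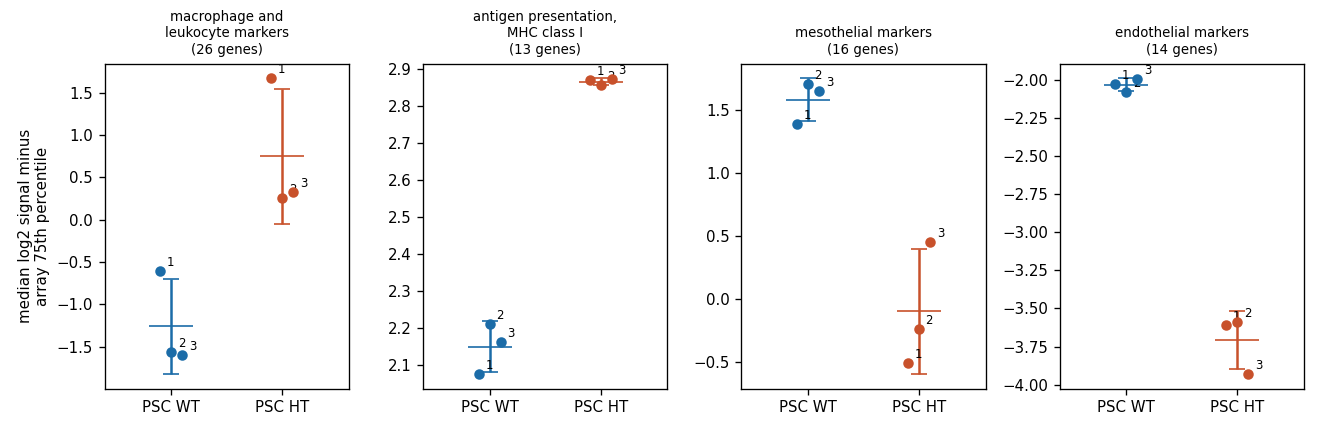
Median log2 signal minus the array's 75th percentile over the tested members of 4 gene lists, per array (points, numbered by replicate), with group mean (line) and SD (bars), for PSC WT and PSC HT (n = 3 each, y axes differ and do not start at 0). The HT arrays lie above the WT arrays for macrophage and antigen presentation genes and below them for mesothelial and endothelial markers, with median fold changes of 2.42, 0.69, -1.30 and -0.97 (log2).

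p53 target genes fell: 11 of 26 were lower and 0 higher (13 and 0 adjusted over the list alone), with a median of -0.32 (adjusted p = 4.14e-08, adjusted p = 0.343 with an estimated correlation). The median was -0.35 with slide as a block, -0.44 within slide 1 and -0.26 within slide 2. The genes that fell included Perp (-2.85 ± 0.25), a junction protein that epithelia and mesothelium also express, Ddit4l (-1.06 ± 0.08), Pmaip1 (-0.92 ± 0.09, the BH3-only protein Noxa) and Trp53inp1 (-0.91 ± 0.07). All 30 mitosis genes had positive values, with a median of 0.27 (adjusted p = 4.24e-09, adjusted p = 0.55 with an estimated correlation). It was 0.25 with slide as a block, 0.27 within slide 1 and 0.21 within slide 2. None of them passed the threshold alone (0 adjusted over the list alone), and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, had 0.51 ± 0.13 (adjusted p = 0.068). DNA replication genes had a median of 0.13 (adjusted p = 0.00529, adjusted p = 0.751 with an estimated correlation). This was 0.07 with slide as a block, 0.14 within slide 1 and 0.04 within slide 2, with 0 of 33 past the threshold (0 adjusted over the list alone) and Pcna at 0.34 ± 0.10 (adjusted p = 0.107).

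Of 30 genes of glycolysis and hypoxia 7 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.25 (adjusted p = 3.04e-07, adjusted p = 0.343 with an estimated correlation). The median was 0.22 with slide as a block, 0.20 within slide 1 and 0.30 within slide 2. The aldolase Aldoc rose by 0.93 ± 0.13, the peptide hormone Adm by 0.60 ± 0.10 and the glucose transporter Slc2a1 by 0.45 ± 0.07, and the transporter Slc2a3 fell by 1.72 ± 0.16. Cholesterol genes had a median of 0.18 (adjusted p = 7.83e-06, adjusted p = 0.55 with an estimated correlation). It was 0.14 with slide as a block, 0.31 within slide 1 and 0.10 within slide 2, with 2 of 24 higher and 0 lower (4 and 0 adjusted over the list alone). The sterol carrier Stard4 rose by 0.55 ± 0.11. Fatty acid synthesis had a median of 0.16 (adjusted p = 0.0148, adjusted p = 0.55 with an estimated correlation). This was 0.11 with slide as a block, 0.17 within slide 1 and 0.10 within slide 2, with 0 of 19 higher and only Lpin1 lower (-0.48 ± 0.09, 0 and 1 adjusted over the list alone). Adipocyte markers had a median of 0.36 (adjusted p = 0.0267, adjusted p = 0.601 with an estimated correlation). The median was 0.41 with slide as a block, 0.45 within slide 1 and 0.24 within slide 2. Of 8, only Cfd, the complement protease adipsin, rose (2.46 ± 0.15, well above background on 2 of 3 WT arrays), and 0 fell (2 and 0 adjusted over the list alone). The unfolded protein response had a median of 0.07 (adjusted p = 0.0138, adjusted p = 0.411 with an estimated correlation). It was 0.07 with slide as a block, 0.07 within slide 1 and 0.11 within slide 2. Of 23, 1 rose, the chaperone Manf (0.39 ± 0.08), and 0 fell (1 and 0 adjusted over the list alone).

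Genes of activated stellate cells and myofibroblasts had a median of 0.14 (adjusted p = 0.011, adjusted p = 0.616 with an estimated correlation). This was 0.11 with slide as a block, 0.03 within slide 1 and 0.19 within slide 2. Of 22, 3 rose and 0 fell (5 and 1 adjusted over the list alone): the matricellular protein Postn (0.56 ± 0.07), the smooth muscle actin Actg2 (0.39 ± 0.08) and Lmod1 (0.41 ± 0.09), which nucleates actin. The intermediate filament genes Des (-0.44 ± 0.11, adjusted p = 0.0727) and Vim (-0.06 ± 0.13, adjusted p = 0.849), the Hedgehog target Gli1 (0.05 ± 0.10, adjusted p = 0.848) and the galectin Lgals1 (0.16 ± 0.17, adjusted p = 0.673) did not pass. Within slide 1 Col1a1, Gli1 and Lgals1 had the opposite sign (-0.17, -0.15 and -0.18), as did Vim within slide 2 (0.08). Targets of YAP and serum response factor had a median of 0.15 (adjusted p = 0.011, adjusted p = 0.447 with an estimated correlation). The median was 0.12 with slide as a block, 0.06 within slide 1 and 0.21 within slide 2, with 2 of 24 higher and 1 lower (6 and 1 adjusted over the list alone). The clotting initiator F3 (0.67 ± 0.12) and the matricellular protein Ccn1 (0.36 ± 0.08) rose, and the phosphatase Ptpn14 fell by 0.84 ± 0.07. TGF-beta targets had a median of 0.14 (adjusted p = 0.0276, adjusted p = 0.411 with an estimated correlation). It was 0.14 with slide as a block, 0.15 within slide 1 and 0.11 within slide 2. Of 29, 3 rose and 1 fell (4 and 2 adjusted over the list alone), among them the cytokine Il11 (0.57 ± 0.13) and the cell cycle inhibitor Cdkn2b (-0.89 ± 0.10).

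Matrix proteases, inhibitors and crosslinkers had a median of 0.15 (adjusted p = 0.0173, adjusted p = 0.343 with an estimated correlation). This was 0.13 with slide as a block, 0.21 within slide 1 and 0.11 within slide 2. Of 32, 3 rose and 2 fell (4 and 2 adjusted over the list alone). Plau, the plasminogen activator urokinase, rose by 0.55 ± 0.11 and the transglutaminase Tgm2 by 0.49 ± 0.08. The inhibitor Timp3 fell by 1.22 ± 0.07 and the gelatinase Mmp2 by 0.45 ± 0.09. Fibrillar collagen and matrix genes did not pass (median 0.12, adjusted p = 0.0548, 4 of 30 higher and 2 lower, 4 and 3 adjusted over the list alone), nor did Hedgehog genes (adjusted p = 0.71, 0 of 15 higher and 1 lower), galectins (adjusted p = 0.502, 0 of 10 past the threshold) or epithelial genes (adjusted p = 0.269, 2 of 16 higher and 0 lower). The median galectin level stood apart on PSC HT 3, at 1.86 against -0.302 and -0.125 on PSC HT 1 and 2. The median epithelial level was also highest there, at -1.461 against -2.024 and -1.811 on PSC HT 1 and 2 and -1.944 to -1.735 in WT. Transcripts of the cancer cells were present on PSC HT 3, as given below. The epithelial counts include that array, so 0 lower does not show that no epithelial gene fell in PSC HT.

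In all, camera called 19 of 44 lists, 15 higher and 4 lower in HT, against 0 with an estimated correlation and 13 with fry. It called 17 with slide as a block, where 3 of the 19 were lost: DNA replication, cytokines and chemokines, and Schwann cell and nerve markers (adjusted p = 0.0502 to 0.06). A macrophage marker score separates the genotypes (WT -1.42 to -0.722, HT 0.291 to 1.44). With it as a covariate, chosen after seeing the data, mitosis, DNA replication, cholesterol and fatty acid lists turned direction, but such a fit cannot tell genotype from macrophage content. With slide as a block, 1446 genes passed. Within slide 1, with 1 WT array, 0 passed and within slide 2, with 1 HT array, 624, where the spread comes from the other group alone, so these counts do not measure the effect of slide. In 6067 genes the 2 groups did not overlap, where chance gives 10% of genes for 3 against 3. Of other probes of the called genes, 51 of 784 had the opposite sign. The call count rests on single arrays: it was 574 without PSC WT 3, 637 without PSC WT 2, 922 without PSC HT 2 and 1027 without PSC HT 3. On PSC HT 3 the epithelial cadherin Cdh1, a gene of the cancer cells chosen here after its values were seen, read -2.45, against -8.22 to -7.61 on the other PSC arrays.

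The next question was what WT PSC medium changes in the cancer cells. The secreted mucin Muc5b (probe at chromosome 7, 149058931 to 149058990, mm9) fell by 2.80 ± 0.16 (adjusted p = 8.45e-05). Muc5ac (chromosome 7, 149004793 to 149004852), another secreted mucin, fell by 2.28 ± 0.15 (adjusted p = 0.000173). Rhox5, a homeobox gene of the X-linked Rhox cluster, rose by 1.87 ± 0.07 (adjusted p = 2.35e-05) and the serine protease Prss27 by 1.58 ± 0.15 (adjusted p = 0.000692). Of 24 genes of cholesterol synthesis 12 rose by small amounts, for example Cyp51, the sterol demethylase, by 0.43 ± 0.07, though as a list they did not pass with an estimated correlation (adjusted p = 0.413 with an estimated correlation). Muc5b and Rhox5 had -2.79 and 1.84 with slide as a block, -2.66 and 1.80 within slide 1 and -2.93 and 1.89 within slide 2. Of 19636 genes tested, 1169 passed, 550 higher and 619 lower, of which 27 and 120 changed at least 2-fold.

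Aadac, a lipid esterase, was at least 3.52-fold lower, and Pla2g10, a secreted phospholipase, at least 1.82-fold lower. The glucuronosyltransferase Ugt2b36 fell by 2.00 ± 0.12, its relative Ugt2b38 by 1.97 ± 0.14 and the cytochrome P450 Cyp2c65 by 1.95 ± 0.08. Duoxa1, the maturation factor of a dual oxidase, was at least 2.20-fold lower, the protease Adamts15 fell by 2.01 ± 0.11 and Fer1l4 by 2.00 ± 0.07. Among the rises were Rims2 (at least 2.58-fold), a regulator of exocytosis, the protease Prss46 (1.62 ± 0.15, well above background on 2 of 3 controls), the neuropeptide Vip (1.51 ± 0.18, on 1 of 3 controls), Mfap3l (1.34 ± 0.08) and the GPI-anchored Ly6 proteins Ly6g (1.41 ± 0.17), Ly6f (1.27 ± 0.26) and Ly6c2 (1.24 ± 0.09). Tnnt2, cardiac troponin T, rose by 1.41 ± 0.08 on its brightest probe, but its 2 other probes did not rise: 1 gave -0.06 and 1 went from -4.79 to a reading below the floor. The mean over probes, -0.54, rests on that last probe.

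Of 24 cholesterol genes 12 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.30 (adjusted p = 6.78e-12, adjusted p = 0.413 with an estimated correlation). The median was 0.28 with slide as a block, 0.28 within slide 1 and 0.29 within slide 2. The genes that rose included Lss (0.43 ± 0.07), Mvd (0.42 ± 0.08) and Sc5d (0.36 ± 0.07), enzymes of the pathway. Targets of YAP and serum response factor had a median of 0.23 (adjusted p = 1.53e-05, adjusted p = 0.0978 with an estimated correlation). It was 0.25 with slide as a block, 0.21 within slide 1 and 0.26 within slide 2. Of 23, 3 rose and 0 fell (10 and 0 adjusted over the list alone): Ccn1 (0.88 ± 0.09), Ankrd1 (0.85 ± 0.07) and the calponin Cnn2 (0.41 ± 0.08). ATF4 targets of the amino acid stress response had a median of 0.18 (adjusted p = 0.0015, adjusted p = 0.628 with an estimated correlation). This was 0.18 with slide as a block, 0.20 within slide 1 and 0.17 within slide 2. Of 33, 10 rose and 1 fell (15 and 2 adjusted over the list alone), among them Mthfd2 (0.75 ± 0.09, mitochondrial folate metabolism), Atf3 (0.60 ± 0.07), Ddit4 (0.47 ± 0.08) and the alanyl-tRNA synthetase Aars (0.41 ± 0.06), whose mean over probes was -0.08.

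Adipocyte markers fell in WT PSC medium: 3 of 7 were lower and 0 higher (4 and 0 adjusted over the list alone), with a median of -0.36 (adjusted p = 0.000273, adjusted p = 0.0978 with an estimated correlation). The median was -0.40 with slide as a block, -0.47 within slide 1 and -0.27 within slide 2. Lower were the lipid droplet protein Plin4 (-1.72 ± 0.07) and the transcription factors Pparg (-0.71 ± 0.08) and Cebpa (-0.49 ± 0.08). Of 14 complement genes 3 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.19 (adjusted p = 0.00676, adjusted p = 0.628 with an estimated correlation). It was -0.20 with slide as a block, -0.30 within slide 1 and -0.19 within slide 2. C3 (-1.28 ± 0.15) and Cfi (-0.79 ± 0.15) fell and Masp1, a protease of the lectin pathway, rose by 0.62 ± 0.08. Fatty acid synthesis had a median of 0.15 (3 of 19 higher, 0 lower, 4 and 0 adjusted over the list alone, adjusted p = 0.0145, adjusted p = 0.628 with an estimated correlation). This was 0.13 with slide as a block, 0.11 within slide 1 and 0.17 within slide 2. Ribosome biogenesis had a median of 0.11 (1 of 29 higher, 0 lower, 1 and 0 adjusted over the list alone, adjusted p = 0.0107, adjusted p = 0.628 with an estimated correlation). It was 0.10 with slide as a block, 0.11 within slide 1 and 0.11 within slide 2. DNA replication genes had a median of 0.10 (2 of 33 higher, 0 lower, 2 and 0 adjusted over the list alone, adjusted p = 0.0326, adjusted p = 0.707 with an estimated correlation). The median was 0.09 with slide as a block, 0.09 within slide 1 and 0.12 within slide 2. The unfolded protein response had 0.11 (0 of 23 past the threshold and 0 adjusted over the list alone, adjusted p = 0.0425, adjusted p = 0.628 with an estimated correlation). It was 0.09 with slide as a block, 0.13 within slide 1 and 0.11 within slide 2. Epithelial genes did not pass as a list (median -0.04, adjusted p = 0.106), with 2 of 27 higher and 5 lower (3 and 8 adjusted over the list alone).

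Camera called 9 of 43 lists, and only 7 of them with replicate number as a block, against 0 with an estimated correlation and 11 with fry. With slide as a block, 1147 genes passed, within slide 1 (with 1 array in WT PSC medium) 18 and within slide 2 (with 1 control) 0. In 4960 genes the groups did not overlap, where chance gives 10%, and 59 of 585 other probes of called genes had the opposite sign. The count fell to 577 without array 3 of WT PSC medium, 684 without array 2, 736 without array 1 and 729 without control array 1, and camera called 5 lists without control array 2 or without array 1 of WT PSC medium.

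HT PSC medium was then set against the same controls. Muc5b fell by 2.37 ± 0.16 (adjusted p = 0.000281) and Muc5ac by 2.02 ± 0.15, and Rhox5 rose by 1.84 ± 0.07 (adjusted p = 3.32e-05) and Prss27 by 1.64 ± 0.15. Krt25, a keratin of the hair root sheath (probe at chromosome 11, 99177867 to 99178575, mm9), was not well above background in control medium and at least 2.89-fold higher in HT PSC medium (adjusted p = 0.00235). Muc5b and Rhox5 had -2.37 and 1.84 with slide as a block, -2.33 and 1.81 within slide 1 and -2.44 and 1.91 within slide 2. Of the 19636 genes, 1072 passed, 582 higher and 490 lower, of which 26 and 75 changed at least 2-fold.

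Aadac was at least 3.29-fold lower, the retinol dehydrogenase family member Rdh7 at least 1.15-fold and the glucuronosyltransferase Ugt1a10 at least 2.18-fold. Hal, the histidine ammonia lyase (-1.93 ± 0.09), Adh7, an alcohol dehydrogenase that oxidises retinol (-1.75 ± 0.15, well above background on 2 of 3 arrays in HT PSC medium), Ms4a10 (-1.74 ± 0.25, well above background on 1 of 3 arrays), Fer1l4 (-1.71 ± 0.07) and Adamts15 (-1.68 ± 0.11) fell as well. The surface proteins Ly6g (1.47 ± 0.17), Ly6c2 (1.37 ± 0.09), Ly6c1 (1.34 ± 0.10) and Ly6a (1.32 ± 0.10, the stem cell antigen Sca-1) rose, as did Rims2 (at least 1.98-fold) and Mfap3l (1.31 ± 0.08). Tnnt2 rose by 1.36 ± 0.08 on its brightest probe, with a mean over probes of -0.52 that rests on the same dim probe.

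ATF4 targets had a median of 0.25 (adjusted p = 1.15e-07, adjusted p = 0.496 with an estimated correlation). This was 0.25 with slide as a block, 0.32 within slide 1 and 0.19 within slide 2. Of 33, 13 rose and 0 fell (15 and 0 adjusted over the list alone), among them Chac1 (1.17 ± 0.16), which degrades glutathione, Mthfd2 (0.86 ± 0.09) and the asparagine synthetase Asns (0.63 ± 0.09). Cholesterol genes had a median of 0.22 (adjusted p = 1.15e-07, adjusted p = 0.378 with an estimated correlation). The median was 0.22 with slide as a block, 0.21 within slide 1 and 0.23 within slide 2, with 4 of 24 higher and 0 lower (12 and 0 adjusted over the list alone), Cyp51 at 0.36 ± 0.07 and Lss at 0.31 ± 0.07. YAP and serum response factor targets, adipocyte markers and MAPK targets were the lists that also passed with an estimated correlation (adjusted p = 0.0473 each). The first had a median of 0.22 (adjusted p = 3.2e-06). It was 0.22 with slide as a block, 0.19 within slide 1 and 0.23 within slide 2, with 7 of 23 higher and 0 lower (8 and 0 adjusted over the list alone), including Ccn1 (0.86 ± 0.09), Ankrd1 (0.81 ± 0.07) and Ccn2 (0.50 ± 0.07). Adipocyte markers had a median of -0.44 (adjusted p = 5.65e-06). This was -0.44 with slide as a block, -0.47 within slide 1 and -0.40 within slide 2, with 4 of 7 lower and 0 higher (4 and 0 adjusted over the list alone). Plin4 fell by 1.55 ± 0.07 and Pparg by 0.48 ± 0.08, and the glucose transporter Slc2a4 had -0.67 ± 0.14 with 1 of 3 arrays in HT PSC medium well above background.

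MAPK feedback and target genes had a median of 0.16 in HT PSC medium (adjusted p = 0.000157). The median was 0.16 with slide as a block, 0.17 within slide 1 and 0.11 within slide 2, with 6 of 24 higher and 0 lower (8 and 0 adjusted over the list alone), including Egr1 (0.71 ± 0.09), the phosphatase Dusp5 (0.67 ± 0.06), Ier3 (0.38 ± 0.07) and Myc (0.35 ± 0.07). Immediate early genes had a median of 0.24 (adjusted p = 0.000157, adjusted p = 0.183 with an estimated correlation). It was 0.24 with slide as a block, 0.28 within slide 1 and 0.09 within slide 2. Of 24, 10 rose and 1 fell (14 and 1 adjusted over the list alone): Atf3 (0.68 ± 0.07) and Fosb (0.63 ± 0.09) rose and Klf4, a factor of epithelial differentiation, fell by 1.26 ± 0.08. TGF-beta targets had a median of 0.17 (adjusted p = 0.000581, adjusted p = 0.305 with an estimated correlation). This was 0.17 with slide as a block, 0.18 within slide 1 and 0.23 within slide 2, with 6 of 28 higher and 1 lower (10 and 2 adjusted over the list alone), among them the transcription factor Bhlhe40 (0.49 ± 0.06).

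Of 9 galectins 1 fell, Lgals2 (-0.62 ± 0.09), and 0 rose (2 and 0 adjusted over the list alone), with a median of -0.19 (adjusted p = 0.00669, adjusted p = 0.496 with an estimated correlation). The median was -0.19 with slide as a block, -0.22 within slide 1 and -0.15 within slide 2. Of 14 complement genes 2 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.0317, adjusted p = 0.496 with an estimated correlation). It was -0.18 with slide as a block, -0.12 within slide 1 and -0.29 within slide 2, and C3 fell by 0.93 ± 0.15. Of 9 genes of MHC class I and antigen presentation 1 rose, H2-K1 (0.33 ± 0.06), and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.19 (adjusted p = 0.0317, adjusted p = 0.496 with an estimated correlation). This was 0.19 with slide as a block, 0.23 within slide 1 and 0.10 within slide 2. p53 targets had a median of 0.10 (adjusted p = 0.0317, adjusted p = 0.305 with an estimated correlation). The median was 0.10 with slide as a block, 0.17 within slide 1 and 0.07 within slide 2, with 3 of 25 higher and 1 lower (3 and 1 adjusted over the list alone), including Gadd45a (0.75 ± 0.07) and Gdf15 (0.73 ± 0.16). The unfolded protein response had a median of 0.13 (adjusted p = 0.0111, adjusted p = 0.496 with an estimated correlation). It was 0.13 with slide as a block, 0.10 within slide 1 and 0.13 within slide 2, with 1 of 23 higher (Edem1, 0.30 ± 0.07) and 0 lower (0 adjusted over the list alone).

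Camera called 12 of 43 lists, against 3 with an estimated correlation and 8 with fry. With slide as a block, 1275 genes passed, and 0 did within slide 1 (with 2 arrays per group) or within slide 2 (with 1 per group). In 4790 genes the groups did not overlap, where chance gives 10%, and 64 of 549 other probes of called genes had the opposite sign. The count was 481 without array 1 of HT PSC medium, 533 without array 3, 645 without array 2, 534 without control array 1 and 585 without control array 2.

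**Figure D3:**
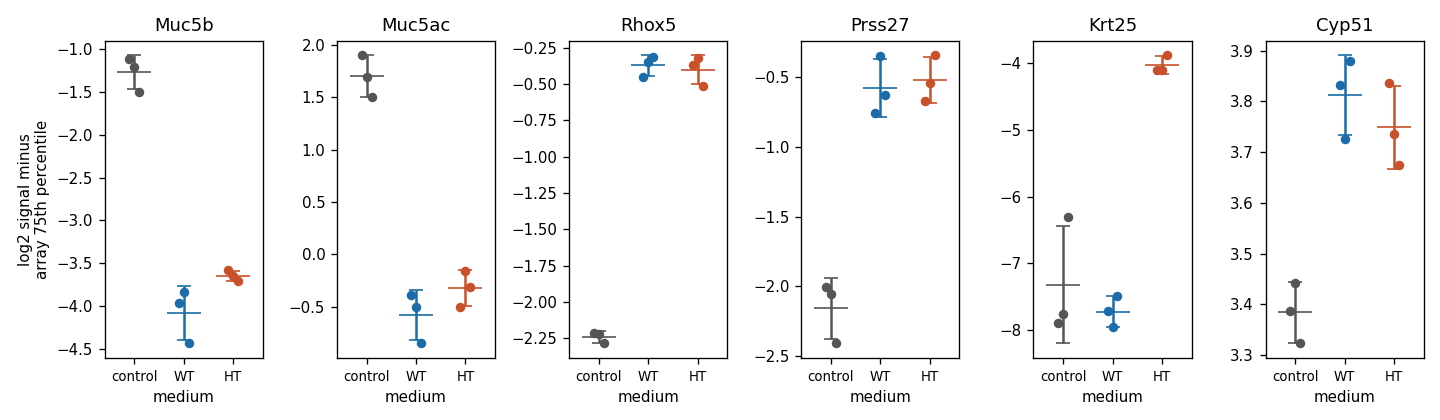
Log2 signal minus the array's 75th percentile of 6 named genes in cancer cells in control, WT PSC or HT PSC medium, per array (points), with group mean (line) and SD (bars, n = 3 each, y axes differ and do not start at 0). Muc5b and Muc5ac are lower and Rhox5, Prss27 and Cyp51 higher in both PSC media than in control medium, and Krt25 stands at -4.02 in HT PSC medium against -7.72 in WT PSC medium and -7.32 in control, where it was not well above background.

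Taking the mean of both PSC media against control (6 arrays against 3), the strongest calls were in genes already named. Rhox5 rose by 1.86 ± 0.06 and Prss27 by 1.61 ± 0.13, while Muc5b fell by 2.59 ± 0.14, Muc5ac by 2.15 ± 0.13, Hal by 1.89 ± 0.08, Fer1l4 by 1.86 ± 0.06, Ugt2b38 by 1.79 ± 0.12, Adh7 by 1.78 ± 0.13 (well above background on 4 of 6 medium arrays), Cyp2c65 by 1.78 ± 0.07 and Plin4 by 1.64 ± 0.06. In all, 1697 of 19636 genes passed, 910 higher and 787 lower, of which 26 and 99 changed at least 2-fold. With slide as a block, 1818 passed, 39 within slide 1 and 2 within slide 2. The groups did not overlap in 3117 genes, where chance gives 2 of 84 splits for 6 against 3, and 110 of 893 other probes of called genes had the opposite sign. The count was 956 without control array 1 and 1061 without control array 2.

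Of 24 cholesterol genes 12 rose and 0 fell over both media (22 and 0 adjusted over the list alone), with a median of 0.27 (adjusted p = 2.31e-10, adjusted p = 0.318 with an estimated correlation), 0.26 with slide as a block, within slide 1 and within slide 2. Of 23 YAP and serum response factor targets 8 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 0.25 (adjusted p = 4.47e-06, adjusted p = 0.0663 with an estimated correlation). This was 0.26 with slide as a block, 0.23 within slide 1 and 0.25 within slide 2. Of 33 ATF4 targets 13 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 0.20 (adjusted p = 1.56e-05, adjusted p = 0.531 with an estimated correlation). The median was 0.20 with slide as a block, 0.24 within slide 1 and 0.16 within slide 2. The ATF4 target Aars had 0.39 ± 0.05, with a mean over probes of -0.06. Adipocyte markers had a median of -0.36 with 0 of 7 higher and 3 lower (0 and 5 adjusted over the list alone, adjusted p = 1.75e-05, adjusted p = 0.0663 with an estimated correlation). Immediate early genes had 0.20 with 9 of 24 higher and 1 lower (12 and 1 adjusted over the list alone, adjusted p = 0.00285, adjusted p = 0.318 with an estimated correlation), and MAPK targets 0.15 with 5 of 24 higher and 1 lower (10 and 1 adjusted over the list alone, adjusted p = 0.00504, adjusted p = 0.135 with an estimated correlation). Complement genes had -0.16 (1 of 14 higher, 3 lower, 1 and 4 adjusted over the list alone, adjusted p = 0.00805, adjusted p = 0.531 with an estimated correlation). Galectins had -0.14 (0 of 9 higher, 1 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.0165, adjusted p = 0.531 with an estimated correlation). TGF-beta targets had 0.12 (8 of 28 higher, 3 lower, 10 and 3 adjusted over the list alone, adjusted p = 0.0165, adjusted p = 0.531 with an estimated correlation). The unfolded protein response had 0.13 (1 of 23 higher, 0 lower, 1 and 0 adjusted over the list alone, adjusted p = 0.0128, adjusted p = 0.531 with an estimated correlation) and fatty acid synthesis 0.11 (4 of 19 higher, 0 lower, 5 and 0 adjusted over the list alone, adjusted p = 0.0217, adjusted p = 0.531 with an estimated correlation). Ribosome biogenesis had 0.09 (1 of 29 higher, 0 lower, 0 adjusted over the list alone, adjusted p = 0.0263, adjusted p = 0.531 with an estimated correlation). p53 targets had 0.12 (4 of 25 higher, 1 lower, 4 and 1 adjusted over the list alone, adjusted p = 0.0336, adjusted p = 0.325 with an estimated correlation). Camera called 13 of 43 lists, and 8 without control array 2, against 0 with an estimated correlation and 18 with fry.

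Because both media were set against the same 3 controls, their effects were compared with those of simulated unchanged groups. Over 19636 genes, which are not independent replicates, the log2 fold changes correlated with r = 0.81 and rho = 0.746, and 78.9% had the same sign. In 100 simulations with no effect the medians were 0.539, 0.507 and 68.9%, and the ranges of -0.46 to 0.908, -0.435 to 0.896 and 35.3% to 87.0% include the observed values. Only the covariance, 0.0554, lay above its simulated range (-0.0100 to 0.0398, median 0.0126). Each simulation shuffled the deviations of the cancer cell arrays from their group means and gave each array a random sign. Patterns shared between these arrays are therefore kept, so the ranges do not show what shared controls alone would give. Of the genes called higher, 374 were shared between 550 and 582, and of those called lower, 404 between 619 and 490. None (0) was called in opposite directions. The shared controls raise this overlap by design, and the overlap they alone would give was not computed.

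**Figure D4:**
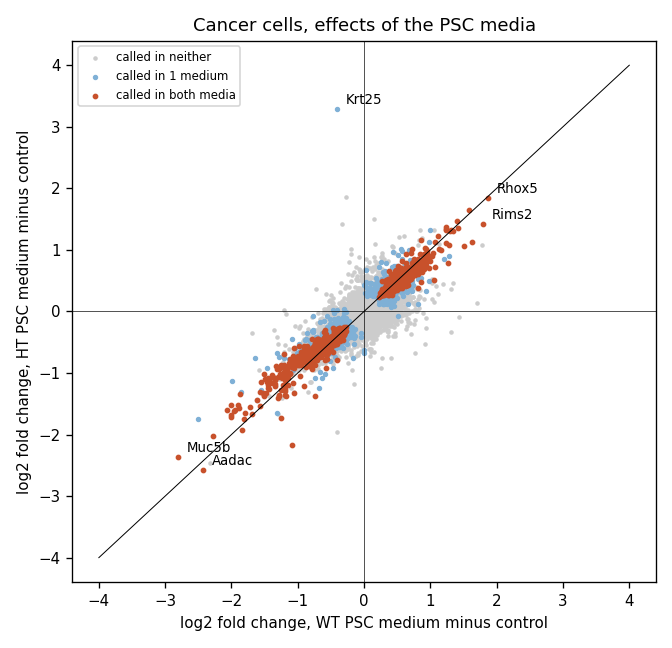
Log2 fold change of each of 19636 genes in cancer cells in WT PSC medium (x) and HT PSC medium (y), each minus control medium (n = 3 arrays per group), coloured by whether the gene passed in neither, in 1 or in both media, with the line of equality. The values correlate with r = 0.81 across genes with shared controls, and Krt25, not well above background in control or WT PSC medium, lies off the line, at least 2.89-fold higher in HT PSC medium than in control.

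HT and WT PSC medium were then compared directly. No gene passed (0 of 19636 by limma) and 960 had an unadjusted p under 0.05. Camera, which tests lists, called 12 of 43, but 0 with an estimated correlation. The gene with the smallest adjusted p was Krt25 (0.12), not well above background in WT PSC medium and at least 2.87-fold higher in HT PSC medium (not past the threshold). Cytokine and chemokine genes had a median of 0.16, with 18 of 21 members positive (adjusted p = 2.36e-06, adjusted p = 0.225 with an estimated correlation). It was 0.15 with slide as a block, 0.26 within slide 1 and 0.07 within slide 2. DNA replication and cholesterol genes had medians of -0.07 and -0.08.

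Genes filled in by smallest unadjusted p, none past the threshold (adjusted p of 0.821 to 0.874), had positive values for the choline transporter Slc5a7 (0.70 ± 0.12), the transcription factor Egr1 (0.48 ± 0.09), the sulfotransferase Sult1d1 (0.40 ± 0.07) and Fndc3a (0.38 ± 0.05, with 2 of 2 other probes opposite). Values were negative for Myo16 (at least 1.45-fold lower), Slc2a4 (-0.67 ± 0.14, well above background on 1 of 3 arrays in HT PSC medium), the water channels Aqp5 (-0.59 ± 0.12) and Aqp2 (-0.34 ± 0.06) and Fbxo2 (-0.43 ± 0.07).

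In the cytokine list, where 0 of 21 passed (2 and 0 adjusted over the list alone), Il1a had 0.57 ± 0.14 (well above background on 2 of 3 arrays in WT PSC medium) and Ccl20 0.44 ± 0.10 (adjusted p = 0.874 each). NF-kappaB targets had a median of 0.10 with 20 of 25 positive (adjusted p = 7.15e-06, adjusted p = 0.239 with an estimated correlation). This was 0.09 with slide as a block, 0.14 within slide 1 and 0.03 within slide 2. None (0) of them passed (2 and 0 adjusted over the list alone), with Vcam1 at 0.40 ± 0.09 and Nfkbiz at 0.31 ± 0.10. Immediate early genes had a median of 0.08 (adjusted p = 0.00046, adjusted p = 0.239 with an estimated correlation). The median was 0.08 with slide as a block, 0.14 within slide 1 and 0.03 within slide 2 (3 and 0 adjusted over the list alone). MAPK targets had 0.08 (adjusted p = 0.000548, adjusted p = 0.217 with an estimated correlation). It was 0.06 with slide as a block, 0.08 within slide 1 and 0.05 within slide 2 (1 and 0 adjusted over the list alone), and theirs was the list that fry called (adjusted p = 0.0209). TGF-beta targets had 0.10 (adjusted p = 0.000286, adjusted p = 0.244 with an estimated correlation). This was 0.06 with slide as a block, 0.08 within slide 1 and 0.05 within slide 2. ATF4 targets had 0.09 (adjusted p = 0.000464, adjusted p = 0.77 with an estimated correlation). The median was 0.06 with slide as a block and 0.14 within slide 1, but -0.04 within slide 2.

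DNA replication genes had a median of -0.07 (adjusted p = 0.0002, adjusted p = 0.77 with an estimated correlation). It was -0.06 with slide as a block, -0.11 within slide 1 and -0.02 within slide 2. Cholesterol genes had -0.08 (adjusted p = 0.0002, adjusted p = 0.77 with an estimated correlation). This was -0.08 with slide as a block, -0.09 within slide 1 and -0.05 within slide 2, with Mvd at -0.21 ± 0.08. Mitosis genes had -0.07 (adjusted p = 0.00334, adjusted p = 0.77 with an estimated correlation). The median was -0.05 with slide as a block and -0.15 within slide 1, but 0.04 within slide 2. Ribosome biogenesis had -0.05 (adjusted p = 0.0221, adjusted p = 0.77 with an estimated correlation). It was -0.04 with slide as a block, -0.04 within slide 1 and -0.03 within slide 2. Growth factors had 0.06 (adjusted p = 0.0192, adjusted p = 0.244 with an estimated correlation). This was 0.06 with slide as a block, 0.06 within slide 1 and 0.01 within slide 2. Matrix proteases had 0.06 (adjusted p = 0.0437, adjusted p = 0.77 with an estimated correlation). The median was 0.04 with slide as a block, 0.08 within slide 1 and -0.04 within slide 2, with the collagenase Mmp13 at 0.53 ± 0.14. In the lists not given a count here, 0 members passed, also adjusted over the list alone. Camera called 0 lists with an estimated correlation and fry 1, and 0 genes passed with slide as a block, within either slide or without any single array of the 2 media (fits without a control array were not run). The call of no gene changes with other choices: normexp, median centring, series matrix values, trend and robust variances, array weights, all 15 arrays in one fit and only the 2 groups compared each called 1 gene, higher in HT PSC medium. The groups did not overlap in 2258 genes, where chance gives 10%.

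PSC WT were last compared with cancer cells in control medium, to describe what each culture expresses. The imprinted RNA Meg3 was at least 6690-fold higher in PSC, the matrix protein Serpinf1 at least 7110-fold, the collagen Col3a1 at least 3850-fold, the crosslinking enzyme Lox at least 4100-fold and the PDGF receptor Pdgfrb at least 992-fold. Col1a1 was higher by 11.94 ± 0.19 and Acta2 by 3.12 ± 0.09. In the cancer cells Wfdc2 was at least 10400-fold higher, the endodermal factor Hnf4a at least 2700-fold, Cdh1 at least 1130-fold and Epcam at least 94.8-fold, and the ductal keratin Krt19 had -7.71 ± 0.10 in PSC minus cancer cells. Col1a1 and Krt19 had 11.94 and -7.74 with slide as a block, 12.29 and -7.88 within slide 1 and 11.60 and -7.60 within slide 2. Of 21885 genes 15623 differed, 7910 higher and 7713 lower in PSC, of which 4547 and 3886 by at least 2-fold.

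Further genes with the largest differences toward PSC were Adamts2 (at least 4240-fold, a procollagen protease), Itga11 (at least 5260-fold, a collagen receptor), Mfap5 (at least 2940-fold), Mgp (at least 2690-fold), Dcn (at least 2340-fold, decorin) and Col1a2 (13.65 ± 0.34, well above background on 1 of 3 control arrays). Toward the cancer cells they were Anxa13 (at least 3400-fold), Gsta2 (at least 2050-fold), Krt23 (at least 1510-fold), Anxa10 (at least 1200-fold), the gastric protease Ctse (at least 1050-fold) and the trefoil factors Tff2 (at least 1040-fold) and Tff1 (-13.10 ± 0.39, well above background on 1 of 3 PSC arrays). Of 30 collagen and matrix genes 28 were higher in PSC and 1 lower (28 and 1 adjusted over the list alone), with a median of 7.67 (adjusted p = 9.88e-11, adjusted p = 0.0622 with an estimated correlation). It was 7.62 with slide as a block, 7.56 within slide 1 and 7.64 within slide 2. Of 22 genes of activated stellate cells 21 were higher and 0 lower (21 and 0 adjusted over the list alone), with a median of 6.65 (adjusted p = 2.91e-09, adjusted p = 0.142 with an estimated correlation). This was 6.64 with slide as a block, 6.44 within slide 1 and 6.83 within slide 2. Thy1 was at least 5830-fold and Des at least 373-fold higher. Of 28 epithelial genes 26 were lower in PSC and 1 higher (26 and 1 adjusted over the list alone), with a median of -5.98 (adjusted p = 9.88e-11, adjusted p = 0.108 with an estimated correlation). The median was -6.05 with slide as a block, -6.26 within slide 1 and -5.92 within slide 2, and the claudin Cldn7 had -7.87 ± 0.08.

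Macrophage and leukocyte markers were also higher in PSC WT than in the cancer cells, with 20 of 26 higher and 2 lower (20 and 2 adjusted over the list alone) and a median of 2.98 (adjusted p = 6.88e-05, adjusted p = 0.344 with an estimated correlation). It was 3.15 with slide as a block, 3.86 within slide 1 and 2.56 within slide 2. Lyz2 was at least 578-fold higher. All 29 mitosis genes were lower in PSC, with a median of -1.34 (29 and 0 adjusted over the list alone, adjusted p = 6.07e-09, adjusted p = 0.148 with an estimated correlation). This was -1.33 with slide as a block, -1.43 within slide 1 and -1.36 within slide 2. Nusap1 had -2.64 ± 0.11 and Bub1b -2.56 ± 0.09. Of 24 cholesterol genes 21 were lower and 1 higher (21 and 1 adjusted over the list alone), with a median of -1.46 (adjusted p = 8.15e-07, adjusted p = 0.108 with an estimated correlation). The median was -1.50 with slide as a block, -1.46 within slide 1 and -1.59 within slide 2. Mesenchymal genes of epithelial-mesenchymal transition had a median of 3.06 (15 of 18 higher, 0 lower, 15 and 0 adjusted over the list alone, adjusted p = 3.21e-05, adjusted p = 0.201 with an estimated correlation). It was 3.14 with slide as a block, 3.42 within slide 1 and 2.86 within slide 2. Sparc (8.75 ± 0.20) and Zeb2 (6.55 ± 0.10) were among them.

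Camera called 29 of 44 lists between the cell types, against 0 with an estimated correlation and 42 with fry. With slide as a block 14979 genes passed, within slide 1 (with 1 PSC WT array) 11080 and within slide 2 (with 1 control) 14234. The groups did not overlap in 16549 genes, where chance gives 10%, and 1078 of 8746 other probes had the opposite sign. Scaling set the balance of directions: with median centring 5322 genes were higher and 10415 lower, and the median of all genes moved by -0.387, and by -0.103 with quantile normalization, relative to the 0.037 of the values given here.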

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

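The alternatives were chosen before the data were examined, except the macrophage marker score as a covariate and leaving out genes at least 4-fold higher in cancer cells, which were chosen after seeing the data. With 3 arrays per group and unequal groups per slide, counts depend on single arrays and on power, and the cause of each difference was not tested.

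Genes changed are given in the order PSC HT against WT, WT PSC medium, HT PSC medium, HT against WT medium, both media and cell types, where these moved. With an adjusted p under 0.10 they were 2568, 1897, 1839 and, for both media, 2678. With a 2-fold limit they were 582, 147, 101, about 1.2e+02 (both media, 26 higher and 99 lower) and 8433 (cell types). With raw p under 0.01 and 1.5-fold they were 542, 459, 29 and 501 from WT PSC medium to both media. With no filter on dim probes they were 398, 467, 333 and, for both media, 732, and 12 lists passed for the PSC and 16 for WT PSC medium, with a correlation between the media of 0.6. The mean of all probes of a gene gave 773, 674 and, for both media, 1128, Tnnt2 -0.54 in WT and -0.52 in HT PSC medium, and Aars -0.08 in WT PSC medium and -0.06 for both media. Every probe on its own gave 23501 for the cell types.

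Median centring gave 637, 534, 1 and 986 from WT PSC medium to both media. Quantile normalization called 13 lists for the PSC, all among the 19 of the main fit, and 5 in WT PSC medium. Normexp background correction, series matrix values, and trend and robust variances each gave 1 gene between HT and WT medium. All 15 arrays in one fit gave 2481 (PSC) and 1 (HT against WT medium), array quality weights 3121 and 1, with Vim at 0.02, and only the 2 groups compared 514 (HT PSC medium) and 1. Estimated correlation called 0, 0, 3, 0, 0 and 0 lists, and fry 1 between HT and WT medium.

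Slide as a block gave 1446, 1147, 1275, 0, 1818 and 14979 genes. Only arrays of slide 1 gave 0, 18, 0 and, for both media, 39, with Col1a1 -0.17, Gli1 -0.15 and Lgals1 -0.18. Only arrays of slide 2 gave 624, 0, 0 and, for both media, 2, with Vim 0.08. The replicate block gave 1138, 964, 789, 0, 1370 and 14329. Whether equal replicate numbers pair arrays is open: residuals correlated at -0.097 to 0.233 (median 0.057) in PSC and -0.302 to 0.442 (median 0.223) in cancer cells, against -0.345 to 0.402 (median -0.025) and -0.524 to 0.391 (median -0.053) for different numbers. Control and WT PSC medium had 0.223, 0.314 and 0.26 for equal numbers, and 7 of the 9 equal-number pairs of cancer cell arrays shared a slide.

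The macrophage marker score separates the genotypes by itself, so as a covariate it cannot tell genotype from macrophage content, and the loss of the macrophage list follows from how it is built. With it 67 genes passed for the PSC, 46 of them among the 1613, and 19 lists (9 higher, 10 lower), only 7 of them among the 19 called without it, DNA replication in the other direction. It turned the direction of the list tests of mitosis (shift -0.06), DNA replication (-0.21), cholesterol (-0.06) and fatty acid synthesis (0.03, so median and test differ in sign), and the signs of Fcgr2b (-0.18), Ccl12 (-0.25), Col1a1 (-0.11), Gli1 (-0.09) and Lgals1 (-0.42). Leaving out genes at least 4-fold higher in cancer cells gave 1369.

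Leave-one-out counts were 574 (without PSC WT replicate 3) to 1412 for the PSC, with 637 without WT replicate 2, 922 without HT replicate 2 and 1027 without HT replicate 3. Col1a1 ranged from -0.06 (without PSC WT replicate 2) to 0.21, Vim from -0.14 to 0.07 (without replicate 1) and Gli1 from -0.02 (without replicate 3) to 0.14. Counts were 577 to 1048 in WT PSC medium (729 without control replicate 1, 736, 684 and 577 without medium replicates 1, 2 and 3), 481 to 919 in HT PSC medium (534 and 585 without control replicates 1 and 2, 481, 645 and 533 without medium replicates 1, 2 and 3), 0 to 0 between the media (leaving out medium arrays only), 956 to 1433 for both media (956 and 1061 without control replicates 1 and 2) and 14123 to 15279 for the cell types. Lists were 17 to 19, 5 (without control replicate 2 or WT PSC medium replicate 1) to 12, 10 to 15, 8 to 17, 8 (without control replicate 2) to 14 and 28 to 30, and the correlation 0.721 to 0.847.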

Other observations

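The tests of cancer cell RNA, of stellate and macrophage shares, of compressed signal and of a weaker HT PSC medium were chosen after the result was seen, and those of background, slide and splits before.

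On PSC HT 3, transcripts of the cancer cells were present. Of 11 genes high in cancer cells and absent from the other 5 PSC arrays, 100% were well above background there, at a median of -6.62 (SD 0.505) relative to the cancer cells, or 1.02% of their level. A higher background on that array would raise absent genes in general, and only 2.57% of 10269 were raised. Cancer cell RNA in that sample, from cells or from handling, could explain this pattern given the 100%. In 86 of the 1613 called genes, 30 of them higher, that RNA would exceed 10% of the level.

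In PSC HT 19 of 26 macrophage markers were higher, and 9 of 16 mesothelial and 8 of 14 endothelial markers lower. None of the 3 lists passed with an estimated correlation, a test that also called 0 of 44 lists between PSC WT and cancer cells. With the other cell types in unchanged proportions, a lower share of stellate cells would raise them all, and the mesothelial median was -1.30. That fall is part of the pattern itself, so a lower share in the HT cultures with changed proportions cannot be excluded. Compressed signal on the arrays with a low spike-in slope, PSC HT 2 and all WT arrays, would put PSC HT 2 near WT. The slope was 0.896 on PSC HT 2 and 0.909 to 0.927 in WT, against 1.05 and 1.06 on PSC HT 1 and 3. Over the 56 members of the 3 lists, PSC HT 2 lay a median of 73.1% of the way to the other HT arrays. Genes outside these lists were not examined for this. A larger share of macrophages in the HT cultures could explain the macrophage part, but was not shown. In both genotypes the markers rose and fell together between arrays (89.5% or more of 19 on the array the others put first). The array with the most was replicate 1 in both genotypes, each on slide 1. PSC HT 3, also on slide 1, had a macrophage marker score of 0.295, near the 0.291 of PSC HT 2 on slide 2. PSC HT 1 had 1.44. In HT the score thus did not follow slide alone, but this rests on 1 array. Joint movement therefore does not separate cell share from slide or other causes. Counting CD45-positive cells by flow cytometry in fresh cultures of each genotype would test the share.

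Of 787 genes that fell over both media, 565 (71.8%) fell less in HT PSC medium, by a median of 0.07. Slide alone would bring the share near 50% with slide as a block, and it was 67.8%. The share was 56.9% within slide 2, which held 1 array in HT PSC medium, so a part for slide cannot be excluded. An HT PSC medium that acts more weakly on all genes would also weaken the rises, and 48.5% of them were weaker. Of 10 splits of the 6 medium arrays 2 had a share as far from 50%, the highest other being 73.4%, and 10 splits are too few for a share under 0.05. The difference may be chance, given those 2 of 10.

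The calls were set against other splits of the same arrays. Where groups differ, splits that mix them put the difference into the spread, so they call few genes by design. Their gene counts therefore do not measure what chance alone would give. With 10 splits, too few for a share under 0.05, as many genes passed in 1 split for PSC HT against WT (1613, highest other 0), 1 for WT PSC medium (1169, highest other 7), 1 for HT PSC medium (1072, highest other 1), 10 for HT against WT medium (0, highest other 0) and 1 for the cell types (15623, highest other 0). As many lists passed in 2 splits (19, highest other 22), 2 (9, highest other 9), 2 (12, highest other 13), 4 (12, highest other 14) and 1 (29, highest other 22).

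For both media against control, with 100 splits, only the real one had as many genes as the 1697 called, the highest other being 1482 in a split that kept the real controls. Splits that did not keep them reached at most 79, a low count that the mixing of groups gives by design. The gene count was therefore not tested against chance. As many lists as the 13 called passed in 15 of 100 splits, with 21 as the highest other, so the number of lists could arise from arbitrary groups of these arrays.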
